A study of Homo sapiens with 5 samples.

How the data were processed

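Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in HCT116, a human colorectal cancer cell line. Cells had been transfected for 48 h with a control siRNA or with an siRNA against ENO1-IT1, a long noncoding RNA named for lying within an intron of the enolase 1 gene, ENO1. The antibodies were raised against histone H3 acetylated at lysine 27 (H3K27ac), a mark of active promoters and enhancers, and against KAT7, a MYST-family histone acetyltransferase also called HBO1. A library of input DNA, taken without antibody, made the fifth sample, and its label does not say which siRNA its cells received. Each group held 1 library. Groups were taken from the sample titles. The codes in the peak names begin with the letters KO in the control and knockdown libraries alike, so they do not tell which cells received which siRNA. If the titles of the conditions had been exchanged, every direction given between control and knockdown would be turned. The lists hold no transcript levels, so the knockdown itself was not checked.

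Reads were aligned to hg19 with Bowtie and peaks were called with MACS2, per the submitters' processing notes. The versions, the calling options and the control used for calling are not given in the sources used here. The peak names in the deposited files carry a tag for duplicate removal, and each list belongs to 1 sample. Each deposited list gave 1 summit of 1 bp per peak, with a chromosome, a position and a score. The score was deposited by the authors as a -log10 p or q value, as MACS2 writes it, and which of these it is was not stated. The lowest scores in the 4 immunoprecipitated lists lay just above 1.30, the -log10 of 0.05. The lowest in the input list was 5.24. A score of this kind grows with sequencing depth, so scores were used to rank or filter summits within a list. Where the same score minimum was applied to several lists, or scores of several lists stand side by side, the values are not on a common scale and show no change in enrichment. The depth of each library is unknown, because the lists hold no read counts.

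Lists were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plotted with matplotlib 3.10.9. A summit was called shared when the other list held a summit at most 500 bp away, and near input when an input summit lay at most 1000 bp away. Shares carry exact Clopper-Pearson 95% intervals. These cover counting error only, since neighbouring summits are not independent and reads may be PCR copies. Chance levels came from 100 circular shifts of the second list, with 1 random offset per chromosome within the span of its summits. With 1 library per group no comparison between siRNAs could be tested against replicate error, and no p-value is given. A difference therefore describes these libraries. The overlap code was tested on simulated lists. For KAT7-sized lists of 122439 summits with 9.82% of positions kept it gave 10.5%. For H3K27ac-sized lists of 29429 summits with 70.0% kept it gave 72.7%, so that it overstated the share somewhat. For the class comparison described next, simulated shares of 80% and 50% were returned as 80.7% and 49.1%. That simulation used exact positions, with parts of the control H3K27ac list in place of the KAT7 and knockdown lists. It checked the division into classes and the averaging, and not how the comparison behaves at 500 bp between different lists.

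To ask whether H3K27ac positions were kept less often where KAT7 was no longer listed, control H3K27ac summits were divided by whether KAT7 was listed within 500 bp in both KAT7 lists, in either list alone or in neither. The share kept was then averaged over 5 equal classes of the control H3K27ac score, so that classes were compared at like scores. Regions named in the text are, for each mark, the 5 highest-scored summits listed in the control only, in the knockdown only and in both. Positions are hg19 and count from 1.

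Before the data were examined, the tests, the alternatives and the rule for named regions had been fixed. The alternatives were distances of 100, 250, 1000 and 2000 bp, score minimums of 10 and 20, and of 50 for the list lengths, distances of 500 and 5000 bp from input, lists of equal length, merged summits, removal of summits near input and restriction to chromosomes 1 to 22 and X. The ratio of list lengths at each score minimum, the score minimum of 3, the removal of sites found in all 4 immunoprecipitated lists, the distances between KAT7 and H3K27ac summits, the split of KAT7 summits by H3K27ac, the class with KAT7 after knockdown only, the classes of score, the lists of the 1000 highest scores, the sites with both marks in 1 condition, the ratios per chromosome, the 1 Mb windows and the clusters of H3K27ac summits were chosen after seeing the data. Promoters, gene lists and the extent of ENO1 were not analysed here, because no hg19 gene annotation was used. The only gene table used was RefSeq for GRCh38.p14, which gave the chromosome of ENO1 and its other names.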

Results

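The data were 5 lists of ChIP-seq summits from HCT116 colorectal cancer cells, covering H3K27ac and KAT7 after control siRNA and after ENO1-IT1 siRNA, and input DNA. The design addressed whether KAT7 occupancy and H3K27ac across the genome changed when ENO1-IT1 was knocked down. The control H3K27ac list held 29429 summits and the knockdown H3K27ac list 31839. The control KAT7 list held 122439 summits and the knockdown KAT7 list 24611. The input list held 945. There was 1 library per group and no replicate, so the differences given here describe these libraries and carry no test against replicate error.

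KAT7 was listed at far fewer positions after ENO1-IT1 knockdown, and most positions differed between the lists. The control list was 4.97 times as long as the knockdown list. Of the control KAT7 summits, 6.62% (95% interval 6.49 to 6.76%) had a knockdown KAT7 summit within 500 bp, against a chance level of 0.811%. Of the knockdown summits, 32.2% (31.6 to 32.8%) had a control summit, against 3.99% by chance. Positions present in both lists were thus 8.17 and 8.07 times as frequent as chance gave, and 114329 control summits had no counterpart after knockdown. The length of the shorter list limits the control share. With the highest-scored summits of both lists at equal length the shares were 12.8% and 13.0%. The same difference in length held on each of the 23 chromosomes counted, chromosomes 1 to 22 and X, where the ratio of knockdown to control summits ran from 0.143 on chromosome 4 to 0.381 on chromosome 22. That each ratio lay below 1 largely follows from the total list lengths and is no further support. Summits of all scores were counted.

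The control KAT7 summits were mostly weak calls. A single score, 2.68, was shared by 52298 of them and another, 1.31, by 26261, together 64.2% of the list. The corresponding share for the most frequent pair of scores was 19.6% in the knockdown KAT7 list and 7.10% in the control H3K27ac list. The direction of the difference in list length depended on the score minimum. At a score of at least 3, 34660 control and 23447 knockdown summits remained. At a score of at least 10, the order was turned, with 3371 control and 9199 knockdown summits, a knockdown to control ratio of 2.73.

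**Figure D1:**
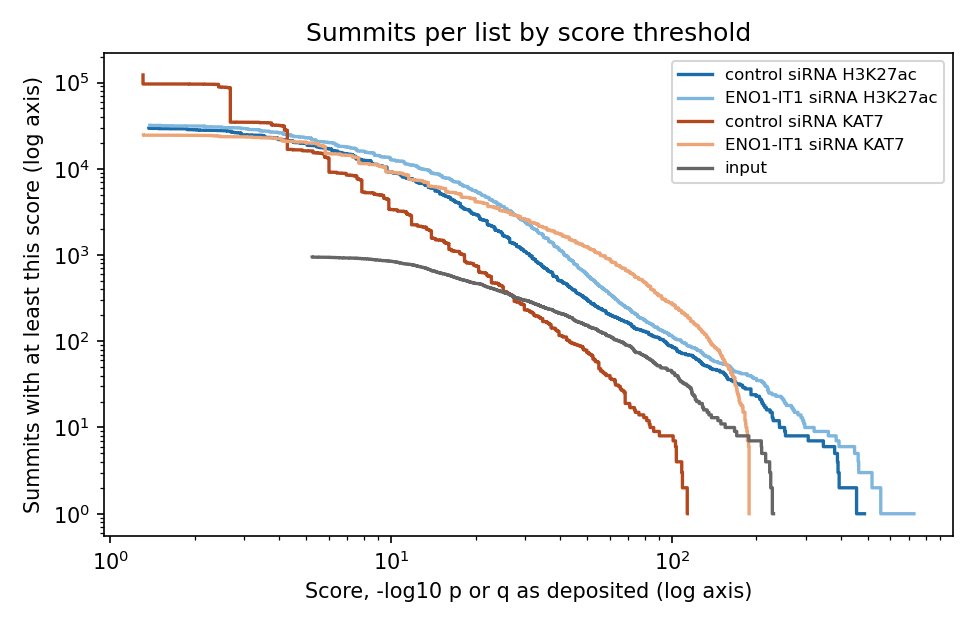
Number of summits (log axis) with at least the score on the x axis (-log10 p or q as deposited, log axis) in each of the 5 lists, 1 library each. The control KAT7 list starts highest, at 122439 summits, drops in large steps at the scores 1.31 and 2.68, and holds 3371 summits at a score of at least 10, against 9199 in the knockdown KAT7 list.

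Strong KAT7 positions were shared more often than weak ones. Of the 751 control KAT7 summits with a score of at least 20, 43.3% (39.7 to 46.9%) had a knockdown KAT7 summit and 426 had none. Of the 4139 knockdown summits with such a score, 68.5% (67.1 to 69.9%) had a control summit and 1303 had none. Among the 1000 highest-scored summits of each list, 22.9% (20.3 to 25.6%) of the control positions were also in the knockdown set. The 5 highest-scored KAT7 summits listed in both conditions lay on chromosome 19 at 4247651, chromosome 10 at 99438703, chromosome 16 at 3899446, chromosome 2 at 102402210 and chromosome X at 53935392. Their control scores were 113.4, 113.4, 109.0, 108.4 and 103.7. Each of these had an H3K27ac summit at most 16 bp away in both conditions.

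The highest-scored KAT7 summit listed in the control only lay on chromosome X at 99283433, with a score of 101.0 and the nearest knockdown KAT7 summit 58754 bp away. The next lay on chromosome 3 at 14222343 (score 86.1), chromosome 13 at 75558071 (score 76.3), chromosome 5 at 61134545 (score 68.2) and chromosome 15 at 55218251 (score 67.2). None of these 5 had an H3K27ac summit within 500 bp in either condition. The nearest was 1754 bp away, at the chromosome 3 position after knockdown. Of the 5 highest-scored summits listed only after knockdown, those on chromosome 19 at 51002156 (score 106.0) and chromosome 9 at 136429515 (score 99.9) lay 630 and 515 bp from a control KAT7 summit, just beyond the distance that counted as shared. The others lay on chromosome 20 at 59524896 (score 81.4), chromosome 3 at 165443312 (score 76.1) and chromosome 7 at 142020871 (score 76.1). The chromosome 3 position was 1 bp from a knockdown H3K27ac summit and 149333 bp from the nearest control one.

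H3K27ac was listed within 500 bp of the same positions in both conditions for most summits. Of the control H3K27ac summits, 71.9% (71.3 to 72.4%) had a knockdown summit within 500 bp, and 64.3% (63.8 to 64.9%) of the knockdown summits had a control summit. Chance gave 1.26% and 1.13%. The shares depended on the distance, with 35.8% and 33.0% within 100 bp and 87.3% and 75.7% within 1000 bp. Within 100 bp the share of knockdown KAT7 summits with a control KAT7 summit was 28.0%, close to that of knockdown H3K27ac. The control lists searched were unlike in length, at 122439 KAT7 and 29429 H3K27ac summits. From the control side the shares within 100 bp were 5.63% for KAT7 and 35.8% for H3K27ac. Across the 2885 windows of 1 Mb that held a summit, the numbers of H3K27ac summits in the 2 lists had a Spearman rho of 0.97, whereas those of KAT7 had a rho of -0.11. These are correlations across windows of single libraries, and windows are not independent replicates. With summits scoring at least 10 the rho was 0.91 for H3K27ac and 0.18 for KAT7, so the sign of the KAT7 value rested on the weak summits. The knockdown list was 1.08 times as long as the control list, and longer on 23 of 23 chromosomes, from 1.04 times on chromosome 17 to 1.21 times (1.10 to 1.34) on chromosome X. On 11 chromosomes the 95% interval of the ratio, which covers counting error only, reached below 1. Chromosomes of single libraries are not replicates, so their common direction adds no support to the total ratio.

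**Figure D2:**
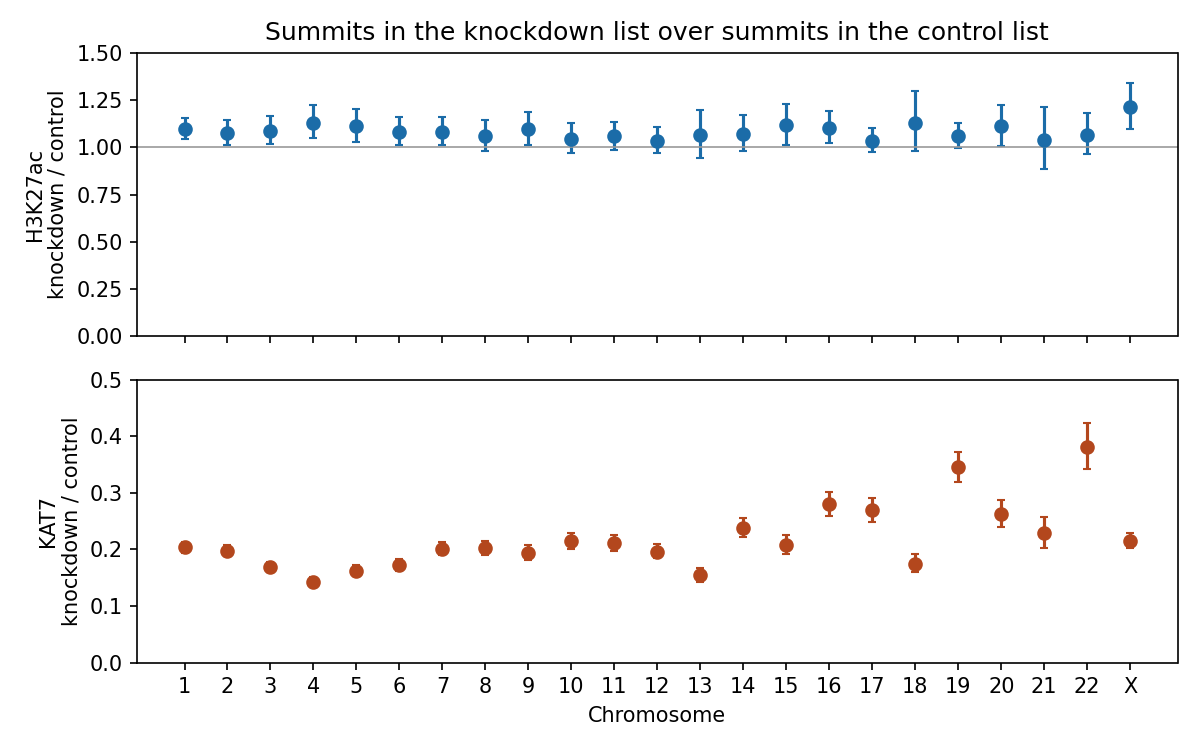
Ratio of knockdown to control summits on chromosomes 1 to 22 and X for H3K27ac (upper) and KAT7 (lower, with its own y axis), with exact 95% intervals for counting error and 1 library per condition. All 23 H3K27ac ratios lie between 1.04 and 1.21, and all 23 KAT7 ratios between 0.143 and 0.381. Summits of all scores are counted.

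The H3K27ac summits found in 1 condition were mostly weak after knockdown and less so in the control. When summits were divided into 10 classes by score, 26.2% of the lowest-scored knockdown class (median score 2.51) had a control summit, against 90.4% of the class with a median score of 15.5. Of the lowest-scored control class (median score 2.19), 57.1% had a knockdown summit, and of the control summits scoring at least 20, 80.1% (78.6 to 81.5%). For KAT7, 82.4% of the highest-scored class of knockdown summits (2518 summits, median score 48.8) had a control summit. Of the highest-scored class of control summits (13228 summits, median score 7.87), 16.0% had a knockdown one. These classes are unlike in size and score, and the knockdown list is the shorter. Of the control KAT7 summits scoring at least 20 and at least 50, 43.3% and 74.3% had a knockdown summit.

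**Figure D3:**
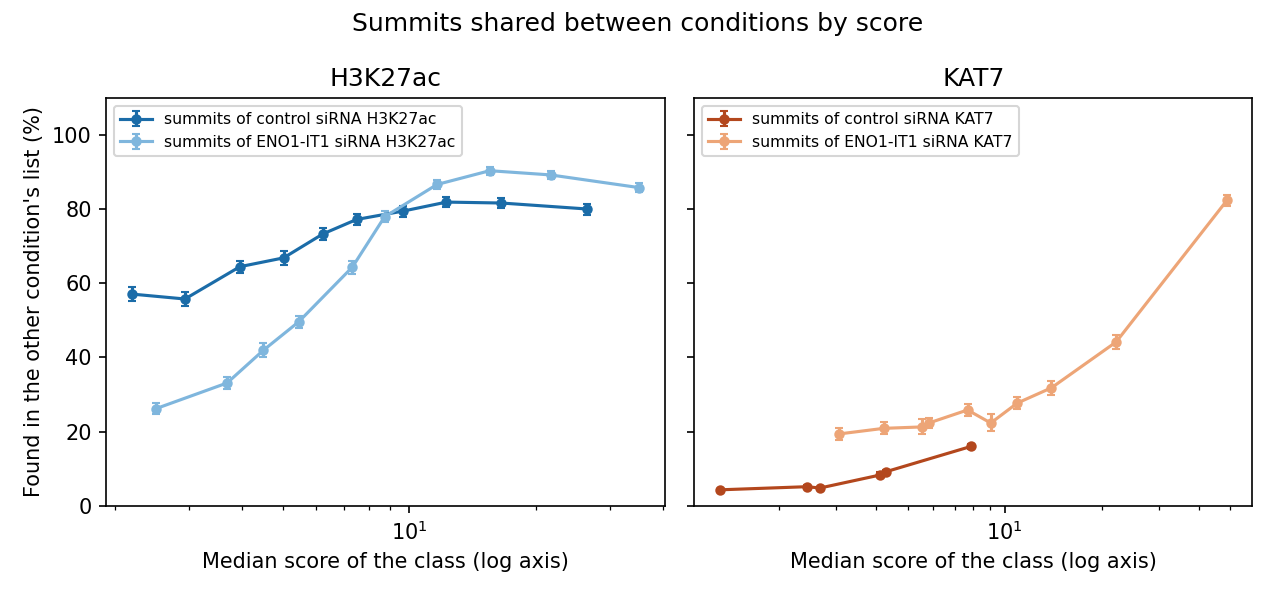
Percentage of summits with a summit of the same mark within 500 bp in the other condition, by class of score (x axis, median score, log axis; 10 classes of rank, fewer where scores tie), with exact 95% intervals for counting error, 1 library per condition. H3K27ac shares lie between 26.2% and 90.4%, and control KAT7 shares stay at or below 16.0%. The highest control KAT7 class has a median score of 7.87, and the highest knockdown KAT7 class 48.8.

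The 5 highest-scored H3K27ac summits of the control list that were also listed after knockdown lay on chromosome 11 at 11268273, chromosome 2 at 1218355, chromosome 15 at 86439644, chromosome 7 at 157254141 and chromosome 18 at 22613640, with control scores from 388 to 485. The control and knockdown positions were 12 to 19 bp apart. All but the chromosome 15 summit were sites found within 50 bp in all 4 immunoprecipitated lists, KAT7 included. The chromosome 15 summit lay 590 bp from a control and 591 bp from a knockdown KAT7 summit. Among the summits listed after knockdown only, the highest was on chromosome 16 at 69439483, with a score of 135, and the nearest control summit was 1546 bp away. Those on chromosome 10 at 114279642 (score 122) and 114276944 (score 97.6) lay on either side of a summit listed in the control only, at 114277890 (score 95.6), so that this stretch was listed in both conditions with different summits. On chromosome 2, the control-only summit at 182655143 (score 80.8) and the knockdown-only summit at 182648595 (score 101) were likewise 6548 bp apart. The remaining summits of these groups lay on chromosome 8 at 126668688 (knockdown only, score 101) and chromosome 3 at 111642708 (control only, score 76.6).

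The highest-scored H3K27ac summits listed in the control only lay together on chromosome 1, at 8937810 with a score of 191 and at 8935949 with a score of 112. They ranked 25 and 71 among the 29429 control summits. The control KAT7 list had summits 6 bp and 1 bp from them, at 8937804 (score 43.2) and 8935948 (score 24.2). Neither knockdown list had a summit within 500 bp. After knockdown, H3K27ac summits were listed nearby at 8938973 (score 42.8), 1163 bp from the first, and at 8935290 (score 4.50), 659 bp from the other. A weak KAT7 summit was listed at 8939346 (score 5.72). H3K27ac was thus still listed in this stretch, at other positions. No input summit lay within 5 kb. ENO1 is on chromosome 1 in RefSeq for GRCh38.p14, where ENO1-IT1 is given as another of its names, and general knowledge of the hg19 map places ENO1 in this part of the chromosome. No hg19 annotation was used here, so the summits were not assigned to exons, introns or the promoter.

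**Figure D4:**
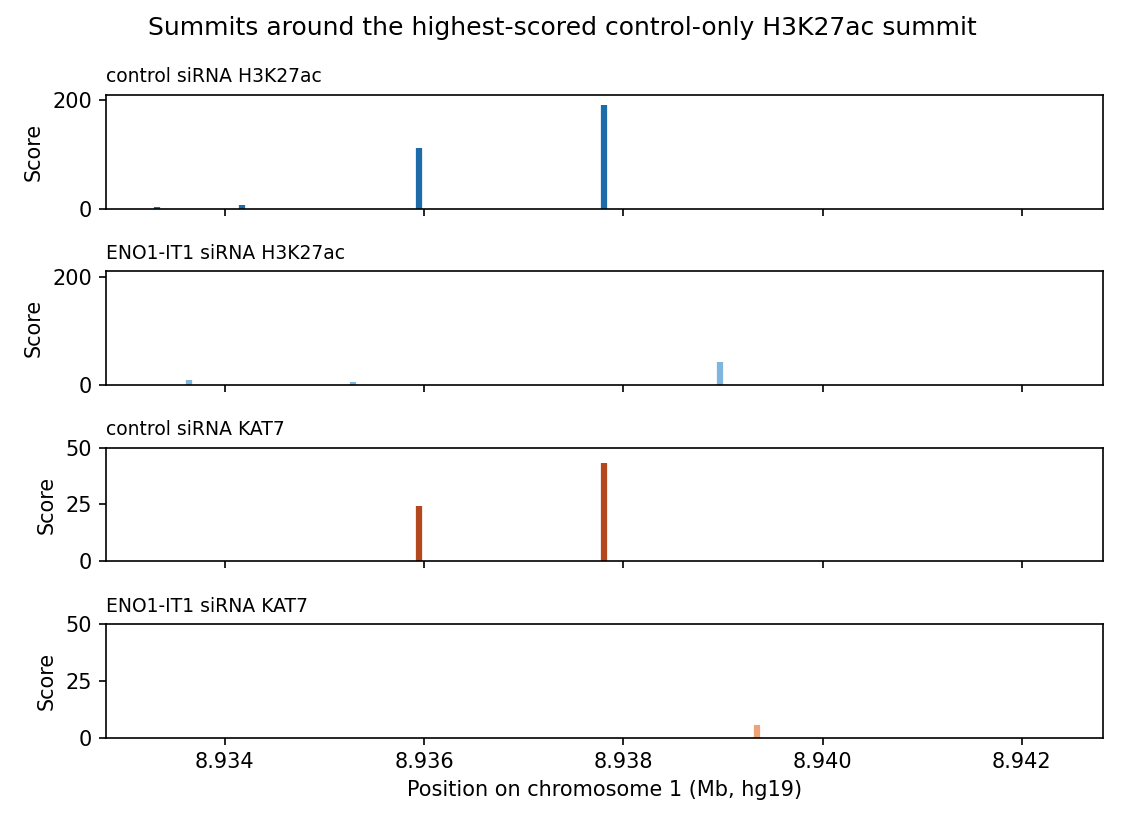
Summits within 5 kb of the highest-scored H3K27ac summit listed in the control only (chromosome 1, position in Mb, hg19), as bars at each summit with its score (-log10 p or q as deposited) as height, in 1 library per panel. The control H3K27ac (191 and 112) and control KAT7 (43.2 and 24.2) bars stand at matching positions that have no bar in the knockdown panels, and heights are comparable only within a panel.

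Sites where both marks were listed in a single condition were counted across the genome. There were 67 control H3K27ac summits with a control KAT7 summit within 50 bp and no knockdown summit of either mark within 500 bp. The chromosome 1 pair held the highest H3K27ac scores among these 67. This was given in advance, because the pair had been chosen as the highest-scored control-only H3K27ac summits. The third, on chromosome 8 at 144680312, scored 37.6. The control-only H3K27ac summits scoring 95.6, 80.8 and 76.6 were not among the 67, since no control KAT7 summit lay within 50 bp of them. The opposite pattern, both marks listed after knockdown only, was found at 319 knockdown H3K27ac summits, with a highest score of 31.9.

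KAT7 and H3K27ac were listed together more often than chance gave in both conditions. In the control, 3.67% (3.56 to 3.78%) of KAT7 summits had an H3K27ac summit within 500 bp, against 0.905% by chance. After knockdown the share was 19.0% (18.5 to 19.5%), against 1.08%. The gap between these shares depended on list length and score. The shares were 6.93% in the control and 16.6% after knockdown with lists of equal length, and, with the same minimum on both marks, 14.6% and 16.3% at a score of 10 and 24.6% and 17.0%, in turned order, at 20. With the minimum on KAT7 alone the order did not turn, at 19.2% and 33.1% for 10 and 36.2% and 56.5% for 20. From the side of H3K27ac, 14.8% (14.4 to 15.3%) of control summits and 14.3% (13.9 to 14.7%) of knockdown summits had a KAT7 summit in the same condition. Chance gave 3.97% with the longer control KAT7 list and 0.860% after knockdown. In the control the share was higher at higher KAT7 scores, with 2.81% for scores under 5 and 68.9% (57.1 to 79.2%) for the 74 summits scoring at least 50. After knockdown it was 15.8% for scores under 5, lower at 10.1% for scores of 5 to 20, 41.2% for scores of 20 to 50 and 92.1% (90.5 to 93.6%) for the 1243 summits scoring at least 50. These strong summits lay on top of each other, with a median distance of 6.5 bp in the control and 8 bp after knockdown among those within 1000 bp. Between the H3K27ac lists of both conditions the median distance was 15 bp for control summits with such scores and 125 bp for those scoring 5 to 20.

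KAT7 summits on H3K27ac were listed again after knockdown far more often than the others. Of the 4492 control KAT7 summits with a control H3K27ac summit, 68.8% (67.4 to 70.2%) had a knockdown KAT7 summit. Of the 117947 without one, 4.26% (4.14 to 4.37%) did. Among summits scoring at least 10 the shares were 95.8% (94.0 to 97.2%) and 8.44% (7.42 to 9.55%). The summits with H3K27ac include the sites found within 50 bp in all 4 immunoprecipitated lists, which are kept by definition. Without those sites the shares were 52.6% (50.8 to 54.4%) and 4.29% over all scores. At a score of at least 10 they were then 73.0% (64.4 to 80.5%) of 126 summits and 8.72% of 2742. Removing the sites lowers the share with H3K27ac by construction.

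Whether H3K27ac was kept less often where KAT7 was no longer listed was not settled. The answer depended on the distance that counted as shared and on sites kept by definition. Of the 2886 control H3K27ac summits with KAT7 in both lists, 85.2% (83.9 to 86.5%) had a knockdown H3K27ac summit. The share was 72.5% (70.2 to 74.8%) of the 1482 with KAT7 in the control only, 69.9% (67.1 to 72.6%) of the 1077 with KAT7 after knockdown only and 70.3% (69.7 to 70.9%) of the 23984 with no KAT7. At like H3K27ac scores the first and second shares were 78.6% and 71.9%, a difference of 6.71 percentage points (95% interval 3.77 to 9.64, normal approximation, counting error only). The first share includes 1385 control H3K27ac summits found within 50 bp in all 4 immunoprecipitated lists. These have KAT7 in both lists and are kept by definition. Without such sites the difference was -5.40 percentage points (-8.81 to -1.99). Removing them lowers the first share by construction, so this does not decide the sign. With them, the difference was 32.0 percentage points at 100 bp, 17.5 at 250 bp and 15.7 with lists of equal length. The same distance set the classes and the share kept. At 1000 bp the shares before the averaging were 89.4% and 88.6%, and at like scores the sign turned, with a difference of -3.40 percentage points (-5.37 to -1.43).

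H3K27ac and control KAT7 summits were spread differently over the chromosomes. Chromosome 19, which is known to be gene-dense, held 6.54% (6.26 to 6.83%) of control and 6.41% (6.15 to 6.69%) of knockdown H3K27ac summits. It held 2.07% (1.99 to 2.15%) of control and 3.55% (3.32 to 3.79%) of knockdown KAT7 summits. Chromosome 4, which is gene-poor, held 1235 of the 29429 control and 4.39% of the knockdown H3K27ac summits, 7.17% (7.02 to 7.31%) of the control KAT7 summits and 5.10% (4.83 to 5.38%) of the knockdown KAT7 summits. Across 1 Mb windows the numbers of KAT7 and H3K27ac summits had a Spearman rho of 0.38 after knockdown and -0.10 in the control. With summits scoring at least 10 these values were 0.24 and 0.20, so the difference in sign was not present among the stronger summits.

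Few summits lay where input DNA itself gave a summit. The share within 1000 bp of an input summit was 0.146% (0.106 to 0.197%) for control H3K27ac, 0.135% (0.0978 to 0.182%) for knockdown H3K27ac, 0.0359% (0.0261 to 0.0482%) for control KAT7 and 0.349% (0.280 to 0.431%) for knockdown KAT7. Chance gave 0.0484% to 0.0539%, below the share of every list except control KAT7. Low shares were given in advance by the 945 input summits, and more so if input was the control in peak calling, which is not stated. They do not exclude background. The gap between the KAT7 lists rested on the weak summits, since at a score of at least 10 the shares were 0.297% (0.142 to 0.545%) in the control and 0.348% (0.238 to 0.491%) after knockdown. From the other side, 98 of the 945 input summits (10.4%) had a knockdown KAT7 summit and 41 (4.34%, 3.13 to 5.84%) a control KAT7 summit within 1000 bp.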

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

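The tests of explanations in this part, and the ratios by score minimum, were chosen after the results were seen. With all summits counted, the list lengths of the marks moved in opposite directions after knockdown, with a knockdown to control ratio of 0.201 for KAT7 and 1.08 for H3K27ac. The opposite direction rested on the weak summits. At a score of at least 5 the ratios were 1.23 for KAT7 and 1.16 for H3K27ac, and at 10 they were 2.73 and 1.39. With 1 library per condition, the difference between the marks was not tested.

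The shorter KAT7 list after knockdown was weighed against weak calling and against a loss of KAT7. Weak calls at the caller's limit may account for the length of the control list. On its own scale this list was made up mostly of low scores, with 106299 of its 122439 summits under 5. The knockdown to control ratio was 0.676 at a score of at least 3, 1.23 at 5 and 2.73 at 10. Why the control list held so many low scores stays open, because scores grow with depth, which is unknown. The turned ratio shows only that the sign rests on the threshold. A loss of KAT7 from its sites would leave strong control summits without a counterpart, and 56.7% of those scoring at least 20 had none, against 19.9% for H3K27ac. The summits without a counterpart lay mostly away from H3K27ac. Of control KAT7 summits scoring at least 10, 95.8% of those on H3K27ac and 8.44% of the others were listed again. Without the sites in all 4 lists these shares were 73.0% and 8.72%. A loss of KAT7 stays open too, because 31.5% of the knockdown KAT7 summits scoring at least 20 also had no counterpart in the control list. No second library shows how far KAT7 lists differ without a knockdown.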

How the results depend on the processing

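Of the alternatives, those with a score minimum of 3, those without the sites in all 4 lists and the ratios of list lengths were chosen after the results were seen. Over 144 combinations of result and alternative, 41 gave a value within the interval of the reported one, or a count within 1.5 times of it, 97 moved further and 6 turned the sign. With 1 library per group no replicate could be left out, and the planned analyses of promoters, gene lists and the ENO1 locus were not run for want of an hg19 annotation. Keeping 1 summit per peak changed nothing, because each peak had a single summit. Removing summits near input and restricting to chromosomes 1 to 22 and X left the shares below within their intervals. Wider distances raise the shares by construction. Removing the sites in all 4 lists lowers them by construction, since those sites are shared in every comparison. For the other alternatives the cause was not tested. Depth, which the lists do not give, limits any reading of scores or list lengths between libraries.

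The share of control KAT7 summits with a knockdown KAT7 summit was 5.63%, 6.12%, 7.42% and 8.85% at 100, 250, 1000 and 2000 bp. It was 11.4%, 22.3% and 36.2% at score minimums of 3, 10 and 20 in both lists, 12.8% with equal lengths, 6.34% with merged summits and 5.49% without the sites in all 4 lists. The share of knockdown KAT7 summits with a control KAT7 summit was 28.0%, 30.2%, 35.2% and 40.3% at 100, 250, 1000 and 2000 bp. It was 17.0%, 8.21% and 6.57% at score minimums of 3, 10 and 20 in both lists, 13.0% with equal lengths, 31.3% with merged summits and 28.1% without the sites in all 4 lists. The share of control H3K27ac summits with a knockdown H3K27ac summit was 35.8%, 56.1%, 87.3% and 93.5% at 100, 250, 1000 and 2000 bp. It was 73.5%, 74.6% and 72.5% at score minimums of 3, 10 and 20 in both lists, 70.1% with equal lengths, 70.7% with merged summits and 70.3% without the sites in all 4 lists. The share of knockdown H3K27ac summits with a control H3K27ac summit was 33.0%, 51.7%, 75.7% and 81.1% at 100, 250, 1000 and 2000 bp. It was 60.8%, 53.5% and 39.0% at score minimums of 3, 10 and 20 in both lists, 67.5% with equal lengths, 60.3% with merged summits and 62.6% without the sites in all 4 lists. The share of control KAT7 summits with a control H3K27ac summit was 2.09%, 2.93%, 4.50% and 5.70% at 100, 250, 1000 and 2000 bp. It was 6.26%, 14.6% and 24.6% at score minimums of 3, 10 and 20 in both lists, 6.93% with equal lengths, 3.25% with merged summits and 2.50% without the sites in all 4 lists. The share of knockdown KAT7 summits with a knockdown H3K27ac summit was 12.4%, 16.4%, 21.0% and 22.7% at 100, 250, 1000 and 2000 bp. It was 18.3%, 16.3% and 17.0% at score minimums of 3, 10 and 20 in both lists, 16.6% with equal lengths, 18.0% with merged summits and 13.9% without the sites in all 4 lists.

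The difference in H3K27ac kept between sites with KAT7 in both lists and in the control only turned to -3.40 and -5.50 percentage points at 1000 and 2000 bp, from 6.71. It was 32.0 and 17.5 at 100 and 250 bp, 12.3, 32.8 and 12.5 at score minimums of 3, 10 and 20, and 15.7 with equal lengths. At the minimums of 10 and 20 few control-only sites remained. A score class that held no such site was left out of the average, so these values may not compare like scores. The value of -5.40 without the sites in all 4 lists does not decide the sign of this difference, because each removed site had KAT7 in both lists and H3K27ac kept by definition. For the same reason these sites raise the 6.71. The KAT7 ratio of knockdown to control summits turned from 0.201 to 2.73, 5.51 and 16.8 at minimums of 10, 20 and 50, and was 0.676 at 3, while the H3K27ac ratio was 1.86 and 1.91 at 20 and 50. At minimums of 10, 20 and 50 the control H3K27ac list held 9194, 2961 and 305 summits. At minimums of 10, 20 and 50 the knockdown H3K27ac list held 12767, 5507 and 584 summits. At minimums of 10, 20 and 50 the control KAT7 list held 3371, 751 and 74 summits. At minimums of 10, 20 and 50 the knockdown KAT7 list held 9199, 4139 and 1243 summits. The input list held 468 and 153 at 20 and 50. The shares near input were 0.221% and 0.188% for control and knockdown H3K27ac and 0.0678% and 0.528% for control and knockdown KAT7 at 5000 bp. At a minimum of 10 they were 0.239% and 0.196% for H3K27ac and 0.297% for control KAT7. At that minimum chromosome 19 held 7.44% and 6.94% of control and knockdown H3K27ac summits and 2.34% and 3.29% of KAT7 summits, and chromosome 4 held 3.74% and 3.91% of H3K27ac and 5.99% of control KAT7 summits.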

Other observations

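All tests in this part were chosen after the results were seen. H3K27ac summits formed dense clusters. When summits at most 10 kb apart were joined, the control list gave 144 clusters of at least 10 summits, with a median length of 29.1 kb. Each of the 144 held at least 1 knockdown H3K27ac summit, 125 held at least 50% as many as in the control, and the median ratio of knockdown to control summits within them was 0.727. Clusters defined in the knockdown list numbered 134, of which 130 held at least 50% as many control summits, and within them the ratio of control to knockdown summits was 0.833, so both ratios lay below 1 for the list that did not define the clusters. The cluster with the most control summits lay on chromosome X from 114960736 to 115004733, with 43 control and 30 knockdown H3K27ac summits. It was followed by clusters on chromosome 3 from 98231843 to 98314016 (41 and 32 summits), chromosome X from 45604730 to 45668191 (37 and 40), chromosome 12 from 76089508 to 76181288 (32 and 28) and chromosome 1 from 8078215 to 8165199 (28 and 29).

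The 1 Mb window with the largest excess of control over knockdown H3K27ac summits was on chromosome 10 from 114 to 115 Mb, with 74 control (exact Poisson interval 58.1 to 92.9) and 54 knockdown summits (40.6 to 70.5). The window with the largest excess of knockdown summits was on chromosome 6 from 30 to 31 Mb, with 58 control and 76 knockdown summits (59.9 to 95.1 for the knockdown). These intervals cover counting error only. The differences between lists had an SD of 2.70 summits over 2885 windows. In 1000 simulations that assigned summits to the lists independently the median extremes were -24 and 33 summits, wider than the observed -20 and 18. Most positions were shared between the lists, which makes such simulations too wide, so they do not decide whether these windows exceed chance.

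The strongest KAT7 summits coincided with H3K27ac summits, and 1377 knockdown KAT7 summits lay within 50 bp of a summit in each of the other 3 immunoprecipitated lists, with a median score of 60.6 against 7.67 for the rest. Background already visible in the input stays open: 0.218% of these sites had an input summit within 1000 bp, but a low share is given in advance if input was the control in peak calling, which is not stated. Enrichment of the same fragments whatever the antibody stays open. Knockdown KAT7 summits scoring at least 50 lay a median of 8 bp from an H3K27ac summit. Control H3K27ac summits with such scores lay 15 bp from a knockdown one, but 64 of the 100 highest-scored are themselves sites in all 4 lists. At scores of 20 to 50, KAT7 lay 11 bp (control) and 10 bp (knockdown) from H3K27ac, against 89 bp between the H3K27ac lists. At scores of 5 to 20 these distances were 23, 161 and 125 bp. Scores of different lists are not on a common scale, so the distances do not decide it. KAT7 and H3K27ac at the same places in chromatin stays open too, because 13.9% of the knockdown KAT7 summits outside these sites had an H3K27ac summit, against 1.03% by chance. A library made with a nonspecific antibody, which would separate these explanations, was not analysed here.

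The chromosome 1 stretch with the highest-scored control-only H3K27ac summits, in the part of the map where ENO1 is known to lie, was weighed as the third pattern. Fewer acetylated histones and less KAT7 there after knockdown may account for it. The highest knockdown H3K27ac score within 5 kb was 42.8, rank 924 in its list, and the control summits ranked 25 and 71 in theirs, but ranks and scores of different lists show no change. DNA from outside the chromatin in the control libraries, such as amplified DNA of this stretch, could also account for it. The KAT7 and H3K27ac summits stood 1 and 6 bp apart, and the next site found in both control lists alone scored 37.6. That the pair ranked first among such sites was given in advance by its choice. The lists hold no reads, so these explanations cannot be told apart.

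In all 5 lists the first summit of chromosome 1 lay between positions 10086 and 10226, at the edge of the telomere, with scores of 12.5 in input, 158 and 227 in control and knockdown H3K27ac, and 28.8 and 120 in control and knockdown KAT7.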
